A study of Mus musculus with 10 samples.

How the data were processed

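The samples were mouse metaphase II (MII) oocytes, the mature unfertilised eggs, of a mixed C57BL6/129 background. The labels put 10 libraries in 3 groups: 4 from 2-month wild-type (WT) females, 3 from 11-month WT females and 3 from 2-month Tet2 knockout (Tet2KO) females. Tet2 encodes a dioxygenase that oxidises 5-methylcytosine. Libraries were made by a low-input bisulfite method, per the labels' protocols. Bisulfite turns unmethylated cytosine into uracil, so that a cytosine still read as cytosine is called methylated. Such a call does not separate methylcytosine from hydroxymethylcytosine, a product of that oxidation, so levels here cover both forms. The labels conflict on the input: the series design speaks of 10 oocytes per sample and the extraction protocol of a single oocyte. Trimmomatic, Bismark (version field 12.5) and the mm10 genome build are named in the submitters' processing notes, without roles or order, and other steps are not given in the sources used here.

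The 3 deposited tables hold a single pooled set of values per promoter window and group, so no value of a single library was used here. Each window is 2000 bp long, extends 1000 bp to each side of an annotated transcript start, and carries an Ensembl transcript identifier. The deposited counts are whole numbers of methylated CpG calls per window, and the deposited coverage is the whole number of all CpG calls in it. The column of unmethylated calls was not read. The deposited fraction is the mean over covered CpG positions of the methylated share at each position. In the 3 tables together, 660 windows had 1 call at every covered position, and in 100% of them the deposited fraction equalled the call share to within 0.001. A further deposited column gives the number of covered CpG positions. The tables list windows with at least 10 calls and 5 covered positions, as their smallest values show. The last line of the 2-month WT table is cut off on the X chromosome, so its windows beyond that point were not analysed here; 28 X windows of the other tables lie there.

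The level of a window was computed as 100 times methylated calls over all calls. This choice was made before any difference between groups was examined, and the deposited fraction served as an alternative. Comparisons used the 40537 nuclear windows listed for all 3 pools. The design fixed before the data were examined foresaw edgeR or limma for values per library and, for pooled values, no test; the pooled branch applied, and no p-value is given. A difference is the level in one pool minus that in another, in percentage points, called points below. Windows 20 points or more apart were counted in each direction. Wilson 95% intervals were computed for levels and Newcombe 95% intervals for differences. These intervals cover counting error only: they hold no spread between animals or libraries, and calls from PCR copies or from neighbouring CpGs of the same read are not independent. The number of windows 20 points apart by counting error alone was simulated in 20 draws from the pooled level of each window. For the age and Tet2KO differences, which share the 2-month WT pool, the correlation was simulated in the same way and recomputed with the 2-month WT calls split at random between the comparisons. Splitting the 4 control libraries was not possible with pooled values.

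The reference table (assembly GRCm38.p6, the build that mm10 represents) gives no Ensembl identifiers and no strand. Windows were therefore named by position: a window took the symbol of each protein-coding or lncRNA gene with a start or end within 200 bp of the window's centre. The 233 genes with windows at both ends were left unnamed. Of the shared windows, 21471 (53.0%) received a symbol, for 15004 symbols. An estimated 0.547% of protein-coding genes may carry the name of a window at their far end. List medians were taken over all windows of a list, so a gene with several windows counts more than once. Counts of list members and values of named members use 1 window per gene, that with the most calls in the pool with the fewest. In the alternative with 1 value per symbol, list medians use the mean over the windows of each gene.

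Named genes followed a rule fixed before the data were examined: per comparison, the 10 highest and the 10 lowest differences, 1 window per symbol, without predicted genes, microRNAs, olfactory and vomeronasal receptors and unnamed cDNA clones. To these came members of each list from the 2 to 4 with the largest absolute difference, some of which are not used here, and Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l and Uhrf1. The 14 lists hold 402 members with a current symbol, of which 286 had a named shared window: maternally imprinted, paternally imprinted, germline, oocyte, spindle and cohesin, DNA repair, antioxidant, mitochondrial, DNA methylation machinery, granulosa and cumulus, pluripotency, polycomb-target, housekeeping and insulin or mTOR genes. The median difference of each list was set against 10000 random lists of the same number of windows, matched on mean level in 10 bins, as a description of these pools. Lists of testis, liver, striated muscle and ribosomal protein genes were added after differences had been seen.

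Alternatives were other thresholds of 10 and 30 points, minima of 20 and 50 calls, autosomes alone, 1 value per symbol, windows of intermediate level, centring on the median, the deposited fraction, thinned calls, windows shared by the compared pools, and removal of windows with a high ratio of 2-month to 11-month WT calls. The counting step was tested on simulated data over the 40537 windows. Of windows changed by 30 points, 95.2% (11-month against 2-month WT), 95.7% (Tet2KO against 2-month WT) and 90.8% (Tet2KO against 11-month WT) were recovered at 20 points. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.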

Results

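DNA methylation at gene promoters was measured in MII oocytes of 2-month WT, 11-month WT and 2-month Tet2KO mice. The pools held 4, 3 and 3 libraries, in that order. The tables held 15046863 CpG calls for the 2-month WT pool, 30431118 for the 11-month WT pool and 8610762 for the Tet2KO pool. Mitochondrial windows took 37.6%, 44.2% and 36.5% of these calls, and they were kept out of all comparisons. Windows can overlap, so these totals and shares can count a call more than once. The median nuclear window held 100 calls in 2-month WT, 159 in 11-month WT and 75 in Tet2KO. At those depths a count of 0 methylated calls allows a level of up to 3.0%, 1.89% and 4.0%. Each pool gave a single value per window, so no difference below has a replicate check, and intervals cover counting error only.

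Most promoters of these oocytes carried little methylation, and a minority was almost fully methylated. Of 40537 shared windows, 58.9% lay under 5% in 2-month WT, 64.2% in 11-month WT and 65.2% in Tet2KO. Windows over 80% made up 11.0%, 11.4% and 11.4%. Windows were also classed by covered CpG positions in the pool that covered most, which depends on depth as well as on sequence. Windows with 5 to 29 averaged 34.7%, 35.9% and 35.5%, while windows with 80 or more averaged 5.21%, 3.96% and 3.67%. Maternally imprinted genes, whose control regions gain methylation during oocyte growth, had 9 windows at 80% or more in 11-month WT and 60% or more in Tet2KO, among them Peg13, Nap1l5 and Mcts2. Their median level was 96.2% in 2-month WT, 97.4% in 11-month WT and 95.2% in Tet2KO. These 9 were chosen as high, so their medians do not describe imprinted genes in general. Over all 37 windows of the 21 measured genes of that list, medians were 66.7%, 72.9% and 76.9% in the same order. H19, methylated on the paternal allele in somatic cells, was at 4.21% of 95 calls, 1.61% of 186 calls and 2.5% of 40 calls.

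**Figure D1:**
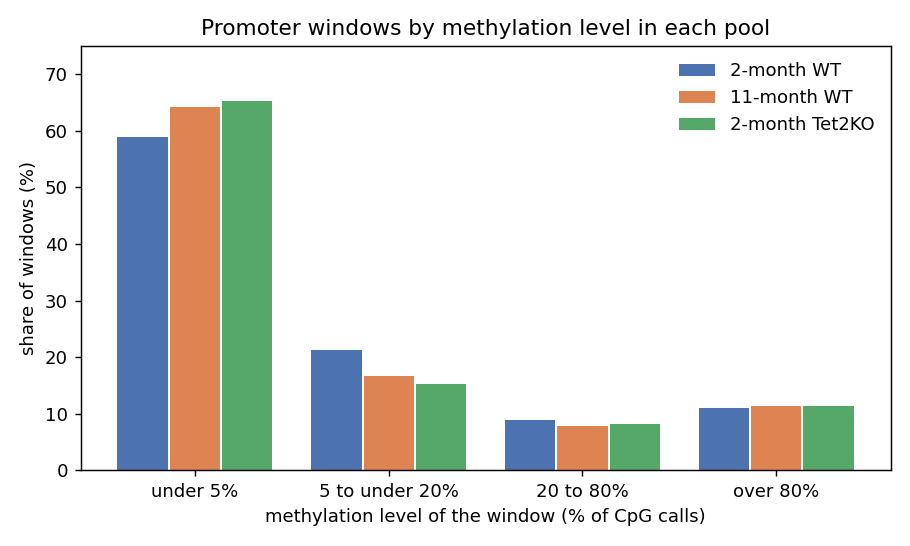
Share of the 40537 shared promoter windows (y axis, percent) in 4 classes of methylation level (x axis, percent of CpG calls), with 1 bar per pool. The class under 5% held 58.9% of windows in 2-month WT, 64.2% in 11-month WT and 65.2% in Tet2KO.

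The knockout comparison begins with the targeted gene. The Tet2 window (chromosome 3, 133544097 to 133546096, mm10) was at 7.84% of 204 calls in 2-month WT (Wilson 95% interval 4.89 to 12.4), 3.41% of 939 calls in 11-month WT (2.42 to 4.77) and 2.59% of 347 calls in Tet2KO (1.37 to 4.86). Methylation around a transcript start does not show whether the gene was deleted, so these values do not check the genotype labels. Dnmt1, the maintenance methyltransferase, was at 2.38%, 3.92% and 0% in 2-month WT, 11-month WT and Tet2KO. Dnmt3l, the cofactor of de novo methylation in oocytes, was at 0%, 3.23% and 1.56%, from 97, 93 and 64 calls. Uhrf1, which recruits Dnmt1, was at 1.62%, 0.632% and 0%. Dnmt3b, a de novo methyltransferase, had a window at 98.3%, 97.6% and 100%. No shared window was named for Tet1, Tet3 or Dnmt3a.

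The comparison of 11-month with 2-month WT oocytes asked how promoter methylation differs with maternal age. At 11 months, 1126 windows were higher by 20 points or more and 1120 were lower. Those among them with a symbol carried 310 and 360 symbols. The highest differences were at Chad, a cartilage matrix protein, at 2.68% in 2-month and 100% in 11-month WT, and at Rdh13, a retinol dehydrogenase, at 3.44% and 97.0%. The lowest differences were at Rps29, a protein of the small ribosomal subunit, at 98.9% and 1.32% of calls, and at Hspa1b, an inducible heat shock protein, at 90.1% and 1.19%. By the deposited fraction the 2-month WT level was 43.6% at Rps29 and 73.5% at Hspa1b. Mean promoter methylation was 17.3% in 2-month WT and 17.0% in 11-month WT, a mean difference of -0.267 points. Counting error alone gave 106.9 higher and 110.5 lower windows in simulation, and the interval of the difference excluded 0 at 1046 of the higher and 1056 of the lower windows. With at least 50 calls in every pool, 212 windows were higher and 468 lower. The mean difference was -1.02 points in those windows, and 1.11 points over every window that each pool lists.

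Other windows high at 11 months lay at genes of several tissues. Filip1l was at 11.1% in 2-month and 98.9% in 11-month WT, and Tie1, an endothelial receptor kinase, at 2.70% and 88.2%. Pla2g10, a secreted phospholipase, was at 5.71% and 91.1%, and its difference of 85.4 points had an interval of 67.9 to 92.2. Ccdc73 was higher by 83.7 points, Shisa7, an auxiliary protein of inhibitory receptors, by 80.7, and Aspg, an asparaginase, by 74.1. Cntn1, a neuronal adhesion protein, was higher by 72.4 points and Smok2b, a kinase of the sperm motility kinase family, by 72.1. The Chad window (chromosome 11, 94564047 to 94566046) rested on 112 and 96 calls, and the Rdh13 window (chromosome 7, 4470286 to 4472285) on 320 and 267. In 2-month Tet2KO, Chad, Rdh13, Filip1l, Tie1, Ccdc73, Shisa7, Aspg and Cntn1 were high as well, at 75% to 100%. Pla2g10 was at 6.45% there and Smok2b at 51.3%. Most of these windows thus set 2-month WT apart from both other pools.

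Windows low at 11 months were named for genes of different functions. Tnp2 and Prm2, which package sperm chromatin, were at 84.2% and 80.3% in 2-month WT and at 2.23% and 0.971% in 11-month WT, from 411 and 508 calls against 179 and 206. Their 2-month WT levels by the deposited fraction were 55.3% and 49.6%. Spesp1, a sperm membrane protein, was at 95.8% of 24 calls and 18.1% of 105 calls. Svs5, a seminal vesicle secretory protein, was at 81.8% of 291 calls (deposited fraction 54.3%) and 5.56% of 36 calls. Insr, the insulin receptor, was at 94.9% of 98 calls and 14.3% of 642 calls (difference -80.6 points, interval -84.4 to -73.6). Ido2, a tryptophan-degrading enzyme, differed by -77.9 points, Prex2 by -75.1 and Bace1, the beta-secretase, by -75.0. The Rps29 window (chromosome 12, 69158295 to 69160294) held 12817 calls in 2-month WT, 453 in 11-month WT and 109 in Tet2KO, so its depth differed with its level. In 2-month Tet2KO, Rps29, Hspa1b, Tnp2, Prm2, Spesp1, Svs5, Prex2 and Bace1 were low as well, at 0% to 5.26%. Insr was at 43.4% there and Ido2 at 47.1%.

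**Figure D2:**
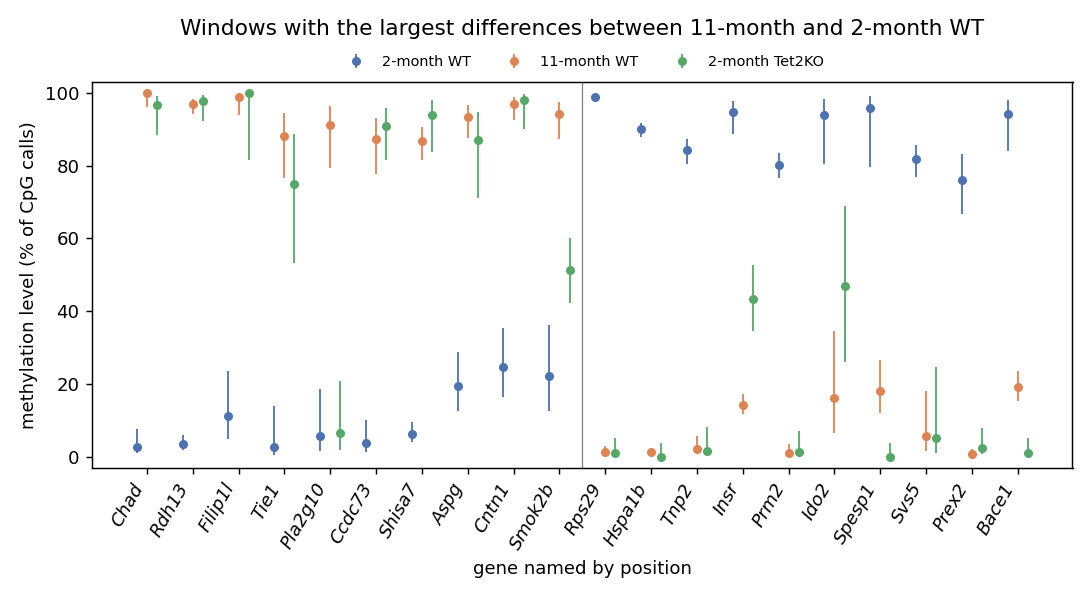
Methylation level (y axis, percent of CpG calls) of the windows with the 10 highest (left of the line) and 10 lowest (right) differences between 11-month and 2-month WT, named by position on the x axis, in all 3 pools. Points are pooled levels and bars are Wilson 95% intervals; Chad was at 2.68% in 2-month WT and 100% in 11-month WT, and Rps29 at 98.9% and 1.32%.

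Gene lists fixed beforehand differed little with age in their medians, while some single members differed by more than 20 points. Of the 14 lists, 2 had a median outside the central 95% of random lists, and none had with 1 value per gene symbol. Antioxidant and sirtuin genes had a median difference of -1.57 points over 54 windows (percentile 0.27), with 10 of 26 members higher and 16 lower. Gpx1, which reduces hydrogen peroxide, was at 76.0% of 1149 calls in 2-month WT, 17.0% of 224 calls in 11-month WT and 7.31% of 219 calls in Tet2KO; its 2-month WT deposited fraction was 53.3%. Prdx5, a peroxiredoxin, differed by -15.8 points with age and Sod1, the cytosolic superoxide dismutase, by -11.4. Insulin, mTOR and ageing signalling genes had a median of 1.22 points over 32 windows (percentile 98.7), while at 1 window per gene 8 of 19 members were higher and 11 lower. The sign of that median turned without windows of high call ratio (-0.181), with at least 50 calls (-0.264) and with 1 value per symbol (-0.264). Ins2, an insulin gene, was higher by 40.5 points at 11 months, from 61 and 38 calls, and Stk11 was lower at -9.99 points.

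The remaining lists lay within the central 95% of random lists for age. Medians were -0.216 points for maternally imprinted genes (percentile 24.8), -3.88 for 3 paternally imprinted genes (14.2), 0.755 for germline genes (96.6) and 0 for oocyte genes (47.9). They were 0.470 for spindle and cohesin genes (89.1), -0.072 for DNA repair (41.9), -0.146 for mitochondrial genes (52.9) and 0.603 for the DNA methylation machinery (93.7). Granulosa and cumulus markers had a median of -1.36 (7.1), pluripotency genes -1.0 (3.17), polycomb targets 0.104 (54.1) and housekeeping genes -1.89 (6.25). Igf2, a paternally expressed growth factor gene, was at 55.2% of 29 calls in 2-month WT and 8.57% of 105 calls in 11-month WT. Mael, which acts in transposon silencing, was lower by -21.9 points and Sycp2, a synaptonemal complex protein, higher by 13.3. Pou5f1, the pluripotency factor Oct4, was at 30% and 1.47%, and Pink1, a mitochondrial quality control kinase, at 36.4% and 2.92%. Gdf9, an oocyte growth factor, was at 15.8% and 2.04%, and Cdc20 and Bub1b, of the spindle checkpoint, differed by -15.2 and -18.0 points. Ptx3 and Inha, of cumulus and granulosa cells, differed by -18.5 and -14.7 points, Wt1 by -10.3 and Tubb5 by -22.4. Zim1, in an imprinted cluster, differed by -12.6 points. By the deposited fraction Zim1 was at 17.8% in both WT pools, and Sycp2 at 52.4% in 2-month and 54.3% in 11-month WT. Most members named here were lower. At 1 window per gene, 16 of 23 spindle and cohesin members were higher and 7 lower, and 14 of 23 germline members were higher and 9 lower. By 20 points or more, 1 housekeeping gene was higher and 2 lower, and 1 methylation machinery gene was higher and 0 lower.

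The comparison of Tet2KO with WT oocytes at 2 months asked how promoter methylation differs with loss of Tet2. Methylated calls cover both methylcytosine and hydroxymethylcytosine, so a shift between these forms would not show in the levels. In Tet2KO, 1332 windows were higher by 20 points or more and 1307 were lower. Those among them with a symbol carried 370 and 430 symbols. Aqr, a splicing helicase, was at 1.05% of 191 calls in WT and 100% of 26 calls in Tet2KO. Rdh13 and Chad, already among the leading windows for age, were at 97.8% and 96.6% in Tet2KO. Rps29, Spesp1 and Bace1 were lower in Tet2KO, at 0.917%, 0% and 0.943%. Mean promoter methylation was 17.3% in 2-month WT and 16.7% in Tet2KO, a mean difference of -0.562 points. Counting error alone gave 223.4 higher and 213.7 lower windows, and the interval of the difference excluded 0 at 1117 higher and 1154 lower windows. With at least 50 calls in every pool, 242 windows were higher and 511 lower, with a mean difference of -1.39 points. Over every window that each pool lists, the mean difference was -2.13 points.

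Further windows high in Tet2KO were those of Filip1l (17 calls), Them7, Shisa7 and Ccdc73, higher by 88.9, 87.8, 87.8 and 87.3 points. Cd4, the T cell coreceptor, was at 2.5% in 2-month WT and 85.2% in Tet2KO. Mgp, an inhibitor of calcification, was at 0% of 77 calls in 2-month WT, 13.1% of 61 calls in 11-month WT and 75% of 28 calls in Tet2KO. Emb, a cell adhesion protein, was higher by 73.8 points. Hspa1b, Tnp2, Prm2 and Svs5 were low in Tet2KO as at 11 months, with differences of -90.1, -82.7, -79.0 and -76.5 points. Car8, a protein related to carbonic anhydrases, was at 86.5% in 2-month WT, 63.1% in 11-month WT and 5.0% in Tet2KO. Bfsp2, a lens filament protein, differed by -77.5 points and H2-M10.4, a histocompatibility gene, by -75.2, the latter from 30 and 14 calls.

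In the gene lists, 4 of 14 medians lay outside the central 95% of random lists for Tet2KO, and 1 with 1 value per gene symbol. That 1 was the pluripotency list (-1.94, percentile 1.01). With 1 value per symbol the others lay within: housekeeping -3.85 (6.03), germline -0.969 (25.8) and DNA repair 0.095 (89.1). Housekeeping genes had a median of -3.85 points over 39 windows (percentile 0.51), with 7 of 23 members higher and 16 lower. Chmp2a and Gapdh differed by -34.8 and -24.7 points and Emc7 by 40.5. By the deposited fraction Chmp2a was at 36.5% in 2-month WT and 14.8% in Tet2KO, and Gapdh at 28.2% and 19.1%. Germline genes had a median of -2.08 points over 37 windows (percentile 0.62), with 9 of 23 higher, 12 lower and 2 equal. Mael differed by -13.3 points and Tex12, of the synaptonemal complex, by 14.0. Pluripotency genes had a median of -1.94 points over 18 windows (percentile 0.78), with Pou5f1 at -30 and Klf4 at -9.52. That median was 0.592 without windows of high call ratio. DNA repair genes had a median of 0.273 over 29 windows (percentile 97.8), with Mlh3 higher by 18.8 points, and 9 of 17 members were higher.

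The other lists lay within the central 95% for Tet2KO. Medians were -0.386 points for maternally imprinted genes (percentile 28.4), -1.71 for paternally imprinted genes (37.6), 0 for oocyte genes (85.0), -0.179 for spindle and cohesin genes (58.5) and -1.44 for antioxidant genes (3.34). They were -0.171 for mitochondrial genes (79.5), -0.106 for the methylation machinery (69.8), -1.01 for granulosa and cumulus markers (25.3), -0.579 for polycomb targets (20.1) and 0.122 for insulin and mTOR genes (89.2). Mcts2, a maternally imprinted gene, was at 92.9% of 42 calls in 2-month WT and 75% of 56 calls in Tet2KO (difference -17.9 points, interval -31.4 to -2.67). Pabpn1l, which acts in the clearance of maternal mRNA, was higher by 25.9 points and Bmp15, an oocyte growth factor, by 17.6. Gpx1 differed by -68.7 points, Pink1 by -35.5, Insr by -51.5, Ptx3 by -20.4 and Lhcgr, the luteinising hormone receptor, by 17.6. Gadd45b differed by -9.33, Hoxd13 by -4.62, Espl1 by 9.12 and Igf2 by -7.55 points, the last with an interval of -32.9 to 19.1.

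**Figure D3:**
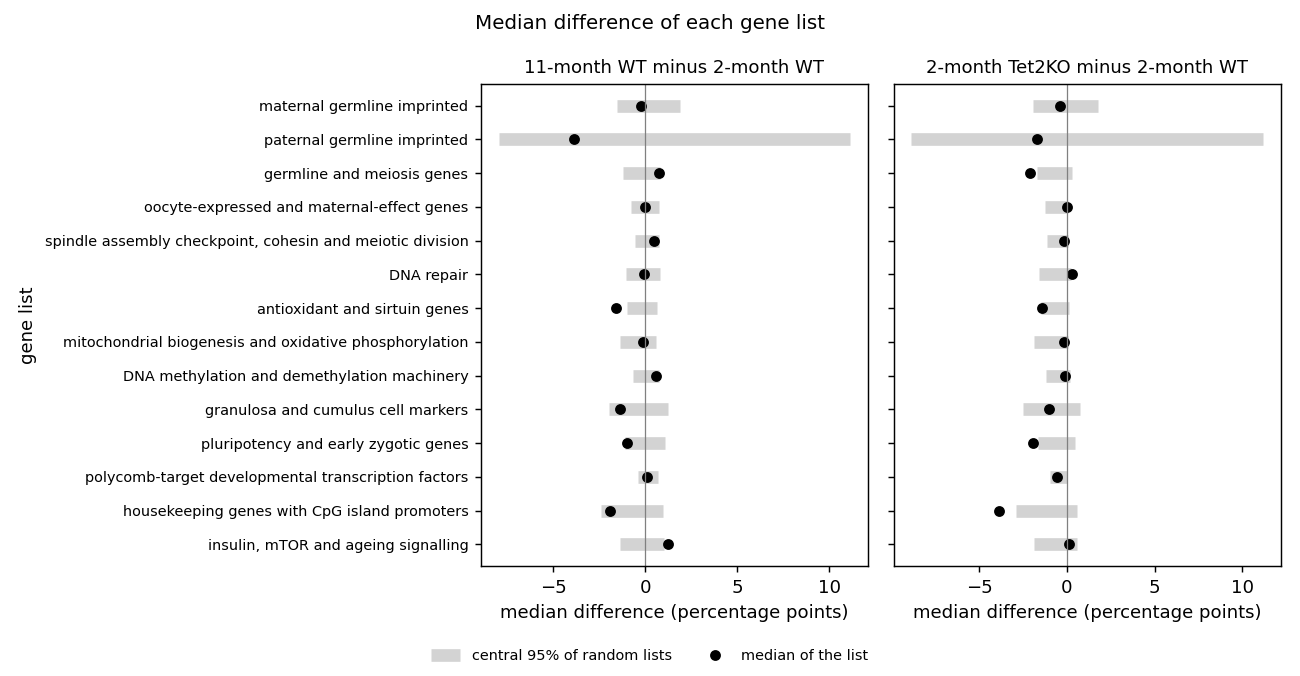
Median difference in percentage points (x axis) over the windows of each of the 14 gene lists (y axis), for 11-month minus 2-month WT (left) and Tet2KO minus 2-month WT (right); grey bars span the central 95% of 10000 random lists. Outside that span lay 2 lists on the left and 4 on the right.

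Tet2KO and 11-month WT oocytes were then compared with each other, 2 groups that differ in both age and genotype. Fewer windows differed than in either comparison with 2-month WT: 847 were higher in Tet2KO by 20 points or more and 788 were lower. Mgp was higher in Tet2KO by 61.9 points, the gene pair Znrd1/Znrd1as by 60.7 and Ttc4 by 55.4, the last from 11 calls in Tet2KO. Znrd1/Znrd1as had 23 calls in Tet2KO, and its deposited fraction was 40% in Tet2KO and 10.7% in 11-month WT. Grip1os1, Ccl21a, Svop, Mrm2, Phyh and Cd52 were higher by 58.3, 53.7, 52.0, 47.4, 47.2 and 47.1 points. Their Tet2KO levels rested on 14, 11, 45, 43, 50 and 13 calls in that order. By the deposited fraction Mrm2 was at 63.0% in Tet2KO and 34.98% in 11-month WT, Svop at 77.2% and 38.7%, and Ccl21a at 72.7% and 30.8%. Pla2g10 and its antisense neighbour Pla2g10os were lower in Tet2KO, at -84.7 and -76.7 points; in Tet2KO the deposited fraction of Pla2g10os was 33.3%, against 14.3% of 28 calls. Sash3, Dpp9, Sbspon, Chd2, Car8, Sorl1, Ldb2 and Aoc1 were lower, with differences from -65.8 to -52.1 points. In that order they rested on 13, 40, 120, 12, 60, 112, 21 and 14 calls in Tet2KO. Counting error alone gave 174.1 higher and 160.8 lower windows.

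The age and Tet2KO differences went the same way at most windows past 20 points in both comparisons. Of the 1126 and 1332 higher windows 606 were shared, and of the 1120 and 1307 lower windows 769, while 26 windows went opposite ways. Independent lists of these sizes would share 37.0 and 36.1 windows, and counting error of the shared 2-month WT calls gave 38.2 and 38.8. Across windows, which are not independent replicates, Pearson's r of the differences was 0.697 and Spearman's rho 0.567. The covariance was 79.1, against 9.87 (r = 0.490) simulated from counting error of the shared calls. With the 2-month WT calls split between the comparisons, the covariance was 69.4 and r was 0.563. Calls could be split but libraries and PCR copies could not, so part of this excess may come from the shared 2-month WT libraries.

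Set against both other pools, the 2-month WT pool stood apart at the most windows. It was higher than both by 20 points at 769 windows and lower than both at 606. These are, by definition, the 769 lower and 606 higher windows shared by the 2 comparisons above, not a further result. The 11-month WT pool was higher at 363 and lower at 203 windows, and the Tet2KO pool was higher at 516 and lower at 279. Of windows under 5% in both other pools, 403 of 23135 reached 20% or more in 2-month WT. In 11-month WT 48 of 20782 did, and in Tet2KO 95 of 20754. Rps29, Hspa1b, Tnp2, Prm2 and Prex2 belonged to the 403 windows.

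**Figure D4:**
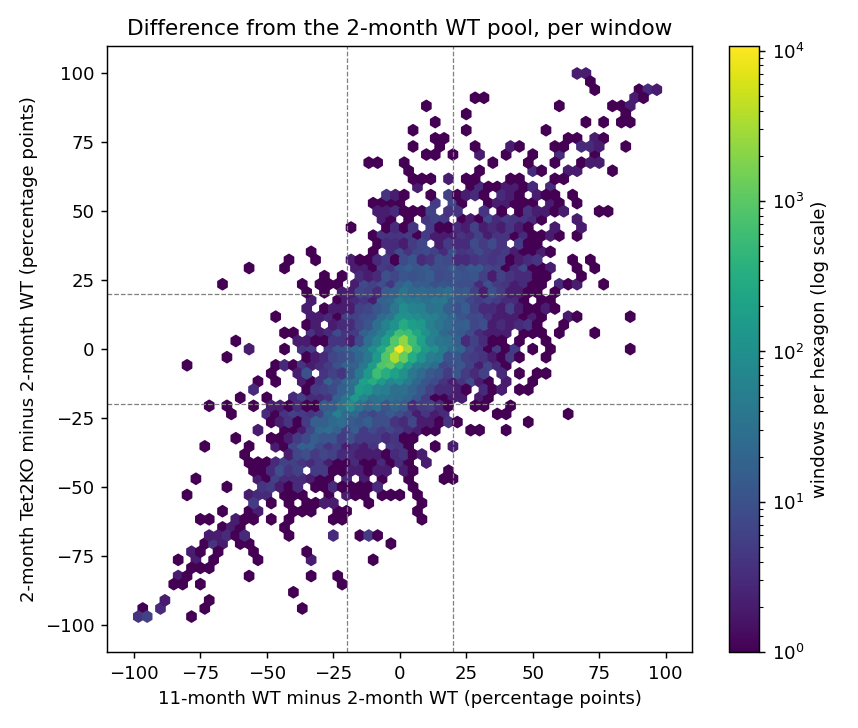
Difference of 11-month WT (x axis) and of Tet2KO (y axis) from 2-month WT, in percentage points, over 40537 windows; colour gives the number of windows per hexagon on a log scale and dashed lines mark 20 points. The cloud lies along the rising diagonal (r = 0.697), with 606 windows beyond 20 points in the upper right and 769 in the lower left.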

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

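The tests of somatic DNA, of library differences and of conversion at nuclear windows, the split by gene length and the call ratio of lower windows were chosen after the results had been seen; the others in this part were fixed before their values were known.

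Windows higher in the 2-month WT pool than in both other pools (769) are by definition those lower in both comparisons. They raised the question of reads that carry unconverted cytosine, such as copies of transcripts. Windows of ribosomal protein genes, which are abundantly transcribed, exceeded the mean of the other pools by a median of 0.618 points (random lists -0.664 to 0.609), where 2 points had been set as the mark of transcripts. The median call ratio of 2-month to 11-month WT over the 769 windows was 1.10 times that of all windows, where 1.5 times had been set. Over the 606 lower windows it was 1.30 times, so median call depth does not separate the sets. Single windows varied. The 2-month WT pool held more calls than 11-month WT at Rps29 (12817 against 453), Svs5 (291 against 36) and Tnp2 (411 against 179). It held fewer at Insr (98 against 642), Prex2 (100 against 581) and Bace1 (51 against 366). Of windows named for genes under 2000 bp, 15.1% were higher by 10 points or more and 6.54% lower, against 6.49% and 4.03% for longer genes; transcript copies could give such an excess, so this explanation stays open. Somatic DNA would lower highly methylated maternally imprinted windows, whose median difference in 2-month WT was 0.942 points (8 windows, -2.67 to 3.83), which argues against it.

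The shared direction of the age and Tet2KO differences could come from the 2-month WT pool that both use. Counting error of independent calls is argued against as the whole source, since r was 0.563 with the calls split. Calls from PCR copies or from the same read can fall in both parts, so the split cannot exclude sampling error that they share. Without windows of high call ratio r was 0.670, which leaves unconverted reads open because median call depth did not separate the higher from the lower windows. A library or batch difference of the 2-month WT pool cannot be told apart from biology, because no other pool of that group was analysed, and a like effect of age and of Tet2 loss stays open. Tet2KO and 11-month WT, which share no control, differed at 1635 windows, fewer than either differed from 2-month WT.

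Mitochondrial windows, which no comparison uses, showed 34.3% methylated calls in 11-month WT, above 27.4% in the 2-month WT control and 24.8% in Tet2KO. Of 37 mitochondrial windows, 31 were highest in 11-month WT. These windows overlap, so they share calls and are not separate observations. Less complete conversion throughout the 11-month WT pool would raise nuclear windows too. Over 19513 nuclear windows under 2% in Tet2KO, the median difference from 2-month WT was 0 points and the mean -1.08 in this test of bisulfite conversion. The reference of this test was the 2-month WT pool, for which unconverted reads stay open, and this limits it. Poor conversion of mitochondrial DNA alone, nuclear copies and age remain possible and were not tested.

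The 11-month WT table lists 3 windows on chromosome Y with 49 calls, 11 of them methylated. The window at 90784586 to 90786585 had 10 of 11 calls methylated, and the others 1 of 27 and 0 of 11. The origin of these calls was not tested, nor whether a window lies in sequence that chromosome X shares. The Tet2KO table lists no window on chromosome Y, and the 2-month WT table ends before that chromosome.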

How the results depend on the processing

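Alternatives with a minimum of 50 calls, the deposited fraction, removal of windows of high call ratio (2-month over 11-month WT), thinned calls, intervals excluding 0 and split calls were chosen after seeing the data. The mean age difference (-0.267 points) was -0.488 with 1 value per symbol, -0.560 at 20 calls, -1.02 at 50 calls, -0.0501 with the deposited fraction, -0.499 without windows of high call ratio and 1.11 over every window each pool lists. The mean Tet2KO difference (-0.562) was -0.811, -0.946, -1.39, -0.721, -0.719 and -2.13 in the same order. For windows each pool lists, the sets differ in their windows by construction; the cause of the other shifts was not tested.

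Counts of windows, given as higher and lower, depend on the filter by construction. For age they were 309 and 354 with 1 value per symbol, 685 and 816 at 20 calls, 212 and 468 at 50 calls, 685 and 809 without windows of high call ratio, 2579 and 3139 at 10 points, and 596 and 506 at 30 points. For Tet2KO they were 362 and 423, 752 and 937, 242 and 511, 883 and 917, 2921 and 3636, and 690 and 587. For Tet2KO against 11-month WT they were 241 and 208, 468 and 483 at 20 calls, 145 and 157, 596 and 516 without windows of high call ratio, 2300 and 2365, and 398 and 344. Centring each pool on its median gave 1168 and 1072 for age and 1426 and 1180 for Tet2KO. The correlation of the differences (0.697) was 0.567 as Spearman's rho, 0.563 with split calls, and 0.670 to 0.786 in the other settings.

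Lists outside the central 95% of random lists numbered 2 for age and 0 with 1 value per symbol. For Tet2KO they numbered 4, with 2 left without windows of high call ratio and 1 with 1 value per symbol. The insulin and mTOR median for age (1.22) reversed to -0.181 without windows of high call ratio, -0.264 at 50 calls and -0.264 with 1 value per symbol. The pluripotency median for Tet2KO (-1.94) reversed to 0.592 without windows of high call ratio. The cause was not tested. In all, 64 alternatives for the main results stayed within their bounds and 48 moved beyond them.

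No paired analysis was possible because the tables hold pooled values without replicates. For the same reason leaving out replicates, fits of 2 groups against 3, other limma settings, a logit scale, estimated correlations and windows measured in 2 libraries per group were not run, and a minimum of 5 calls was not run because the tables start at 10. Depth limits the Tet2KO pool most, where the median window held 75 calls.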

Other observations

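The names in the next paragraph, the added gene lists, the gene families and their values per gene were chosen after values had been seen; the tests of call depth at testis genes and of the Tet2 region were fixed before their values were known.

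Some windows set a single pool apart. In 11-month WT, Pparg, the regulator of fat cell differentiation, was at 63.2% of 231 calls, against 5.18% in 2-month WT and 26.6% in Tet2KO. Sorl1, a sorting receptor, was at 69.7% in 11-month WT, 3.06% in 2-month WT and 15.2% in Tet2KO, and Ptgfr, the prostaglandin F receptor, at 63.1%, 23.6% and 15.7% in that order (deposited fraction 25.8% in Tet2KO). Topaz1, a germ cell gene, was lower at 11 months, at 17.1%, against 71.4% in 2-month WT and 51.1% in Tet2KO. In Tet2KO, Junb, an AP-1 transcription factor, was at 26.6% of 199 calls, against 64.2% in 2-month WT and 67.1% in 11-month WT. Grwd1 was at 1.32% in Tet2KO, 31.6% in 2-month WT and 28.5% in 11-month WT. Phyh, a peroxisomal enzyme of phytanic acid breakdown, was at 58.0% in Tet2KO, 13.7% in 2-month WT and 10.8% in 11-month WT.

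Testis-expressed genes were the added list with the widest difference. Their median over 42 windows was -6.71 points for age and -11.0 for Tet2KO, both below all 10000 random lists, and with 1 value per gene -6.52 (percentile 0.06) and -11.0, with 22 and 20 of 27 members lower. Striated muscle genes had a median over 17 windows of 1.09 for age (percentile 91.9) and 3.85 for Tet2KO (99.98), but 4 of these windows belong to Tnnt2. With 1 value per gene the medians were -1.06 (37.8) and 3.22 (99.04), with 8 of 13 members higher in Tet2KO. Over windows, liver genes had medians of 0 for age (percentile 37.8) and 0 for Tet2KO (77.1), and ribosomal protein genes -0.177 (69.2) and -0.763 (49.4). Among 20 gene families defined by symbol, 8 for age and 3 for Tet2KO lay outside the central 95% of random lists by the median over windows. Core histone genes were among them, with medians of -2.97 for age and -3.44 for Tet2KO over 58 windows, and -1.36 and -2.24 with 1 value for each of 49 genes. Beta-defensin genes had a median of 3.55 for age over 12 windows and 3.58 over 10 genes, and olfactory receptor genes 0.757 over 216 windows and 1.10 over 204 genes.

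A hypothesis for the testis list was that copies of testis transcripts, which would carry unconverted cytosine, reached the 2-month WT pool. The list exceeded the mean of the other pools by a median of 7.16 points over its windows in 2-month WT, and 13 of 27 members exceeded it by 10 points or more. Such copies could add calls at these windows. Their call ratio of 2-month to 11-month WT was 1.41 times that of all windows, between the 1.2 and 1.5 set as bounds, and 11 of 27 members lay above 1.5. Against Tet2KO the same ratio was 1.17, under the lower bound, so the test did not decide, and a difference in methylation stays open.

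A second hypothesis was that sequence from another strain around the targeted gene could set Tet2KO apart, since targeted alleles carry flanking sequence of their origin. Within 20 Mb of Tet2 on chromosome 3, 8 of 551 windows (1.45%) stood apart from both WT pools, against 1.96% of all windows and a central 95% of 0.525% to 3.76% in 1000 random regions. The result argues against a concentration of such windows around Tet2. It does not address strain sequence elsewhere in the genome or in the WT pools, and the samples were of mixed background.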
